A study of Mus musculus with 2 samples.

How the data were processed

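GPS2, a subunit of the nuclear receptor corepressor complexes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 3T3-L1 cells, a mouse preadipocyte line that turns into adipocytes after hormonal induction. The labels give 1 library from day 0 and 1 from day 6 of induction. Per the labels' protocols, the antibodies were raised in rabbit against peptides from either end of the GPS2 protein, and the DNA was sequenced on an Illumina GAII. Which antibody served which library is not given in the sources used here. No input or control immunoprecipitation was analysed here.

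The submitters' processing notes name Bowtie, HOMER and the genome build mm8. Their versions, settings and roles, the peak threshold and any control for peak calling are not given in the sources used here. For each library the authors deposited the aligned reads and a list of windows. The reads were intervals of 36 bases, and no start and strand occurred more than once on a chromosome in either library, so each position counted at most 1 read per strand. The authors' deposited score column of the reads held 1 constant value and carried no measurement. The deposited window lists held positions only, with no height, fold, p-value or gene, and every window was 2000 bp wide. Positions in both kinds of file were read as BED intervals and are given counted from 1.

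From these positions the reads were counted again. The distance at which read starts on opposite strands paired most often outside the windows was 190 bp at day 0 and 170 bp at day 6. Each read start was moved by 95 bp (day 0) or 85 bp (day 6) towards the centre of its fragment. Windows of the lists that overlapped by at least 1 bp were joined into merged windows, and reads were counted in each. RPM, the read count scaled to library size, refers to all reads of the library. The local background was the read density within 5 kb on both sides of a window, outside all windows. Fold over the flank used this density, or the genome mean where that was higher, and sums over groups of windows used windows with at least 2 kb of free flank. The genome background was counted in 10 kb bins lying wholly outside the windows and a margin of 1 kb.

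The labels give no replicates, so no test between days was made and no p-value for a difference between days is given. Ratios of day 6 to day 0 carry exact conditional binomial 95% intervals, shares carry exact Clopper-Pearson 95% intervals, and both cover counting error only. Read pairs of the same molecule copied by PCR cannot be told from independent molecules beyond the limit of 1 read per position, and differences between cultures or immunoprecipitations are not covered. A count of 0 allows up to 3 reads, which is 7.05e-05% of the reads at day 0 and 8.47e-05% at day 6. Before the data were examined, a merged window was set to be called higher or lower at day 6 at a ratio of at least 2 or at most 0.5 with at least 10 reads in the larger library. This rule was tested on simulated data for the 21227 merged windows. The changed windows were drawn only from those above a minimum number of reads over both libraries together. The rule called 49 of 50 windows changed by 4-fold, 48 of 50 reduced to 0.25, 26 of 50 changed by 2-fold and 22 of 50 reduced to 0.5. These rates do not cover windows with fewer reads. The rule also called 8.02% of unchanged windows, so single calls at low counts are not reliable.

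The overlap of the lists was set beside 100 random placements of the day 0 windows on their own chromosomes. Correlations across the 20 chromosomes (the autosomes and X) were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment within each family. The counts of genes per chromosome came from the assembly GRCm38.p6, not mm8, and were used without coordinates. No coordinates were converted between builds.

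The rule for regions to name was written before the data were examined. It took the 10 windows of each list with the highest peak score, and, among windows with at least 20 reads in one library, the 10 largest and the 10 smallest ratios. Because the lists held no peak score, the read count in the list's own library took its place. Windows with the highest fold over the flank, and 500 kb segments with many changed windows, were added after the values were seen. The rule's further parts, on members of fixed gene lists and on Gps2, Kdm4a, Pnpla2 and Lipe, needed a gene annotation of mm8. None was used here, so the planned shares of windows near gene starts, the gene list comparisons and the named genes are not reported, and regions carry coordinates in place of gene names.

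Alternatives set before the data were examined covered the overlap rule, the shift of the reads, the scaling of the libraries, the part of the window counted, the minimum count, the ratio, the local background and the bin size. Others, added after seeing the data, used stricter windows, left out the densest windows or a segment of very dense background, or kept the day 0 list alone. Counting 1 read per position, also set in advance, changed nothing by construction, since the deposited reads already had that form. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.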

Results

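Binding of GPS2 to the genome was measured by ChIP-seq in 3T3-L1 cells at day 0, before adipogenesis was induced, and at day 6 after induction. There was 1 library per day and no replicate, so every comparison below is between these 2 libraries, and its interval covers counting error only. The day 0 library held 4258133 aligned reads and the day 6 library 3543507, which is 0.832 times as many. Of these, 54.1% and 53.8% lay on the plus strand. All positions are in mm8.

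The first comparison asked where GPS2 was found at each stage. The authors' list held 7652 windows at day 0 and 19794 at day 6, 2.59 times as many. Most of the day 0 sites were listed again at day 6: 5529 of 7652 windows overlapped the day 6 list (72.3%, 95% interval 71.2 to 73.3). In the other direction, 5664 of the 19794 day 6 windows overlapped the day 0 list (28.6%, 28.0 to 29.2), which left 14130 day 6 windows without a day 0 counterpart and 2123 day 0 windows without one at day 6. Lists of unequal length give unequal shares by arithmetic, and lists of equal length give nearly equal ones. Among the 5000 windows of each list with the highest fold over the flank (chosen after seeing the data), 50.3% and 50.4% overlapped. Of the full day 0 list it was 72.3%. Random placement of the day 0 windows gave 223 to 309 overlaps in 100 placements, with a mean of 262.65, so the observed overlap was 21.1 times the random mean. The authors called each list on its own library, with thresholds that are not given in the sources used here.

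Joining the lists gave 21227 merged windows. Of these, 5381 were in both lists, 2103 in the day 0 list only and 13743 in the day 6 list only. Chromosome 8 was densest in day 0 windows, with 5.70 per Mb, and chromosome 11 in day 6 windows, with 13.6 per Mb. Chromosome X was sparsest among the autosomes and X, with 0.640 and 1.82 windows per Mb.

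Reads piled up around the window centres, plus-strand starts upstream and minus-strand starts downstream. At the day 0 windows, day 0 plus-strand starts in the 200 bp upstream of the centre stood 15.0 times above the level beyond 1 kb from the centre, and minus-strand starts in the 200 bp downstream 12.3 times. The same windows gave 11.9 and 9.30 times in the day 6 reads, which were not used to choose them. At the day 6 windows the day 6 reads gave 15.4 and 13.4 times, and the day 0 reads 6.82 and 5.51 times. Starts on the opposite side of the centre stood between 3.11 and 5.26 times above the same level. The sharp edges near 200 bp appeared for each list only with its own reads.

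**Figure D1:**
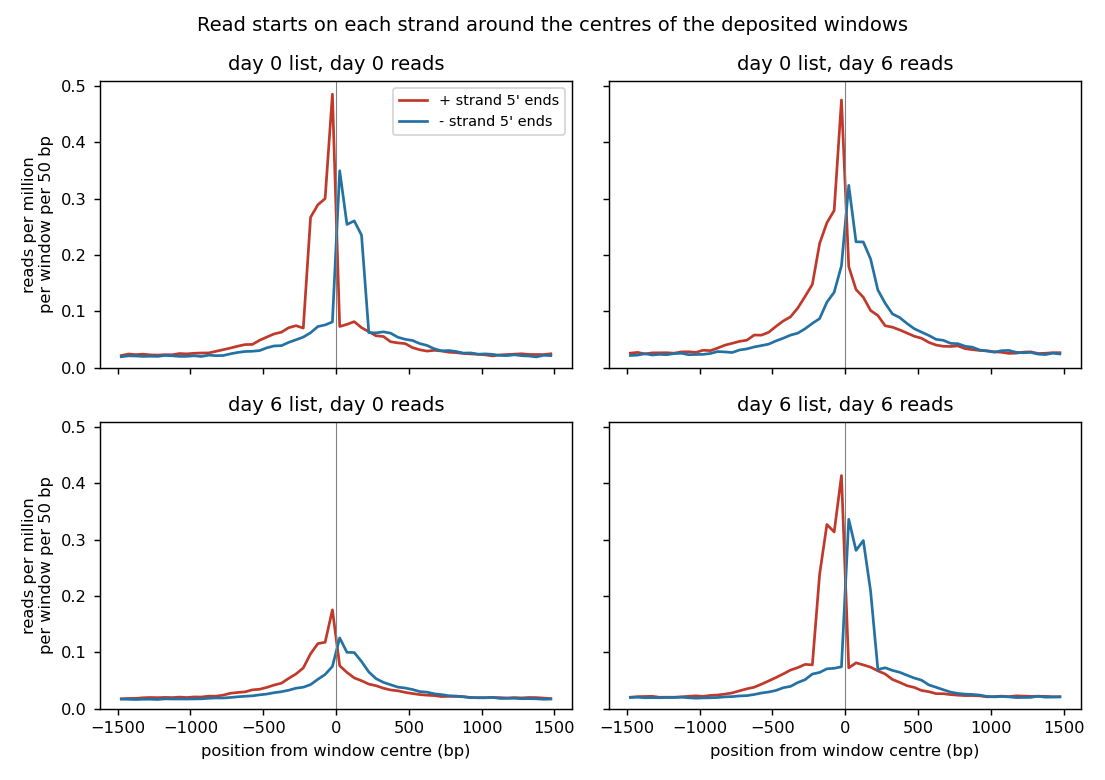
Read starts per window and 50 bp in RPM, reads scaled to the library size (y axis), against the position from the window centre in bp (x axis), for each list (rows) with each library's reads (columns). Red lines are plus-strand starts and blue lines minus-strand starts. Plus-strand starts of the day 6 reads average 11.9 times the outer level in the 200 bp upstream of the day 0 window centres. Those of the day 0 reads average 6.82 times at the day 6 windows, which form a longer list.

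The next comparison asked how much of each library lay in bound regions. The day 0 list held 4.24% of the day 0 reads (180520 reads, 4.22 to 4.26) in 0.579% of the genome. The day 6 list held 10.9% of the day 6 reads (385298 reads, 10.8 to 10.9) in 1.495% of the genome. In the same merged windows, which covered 1.70% of the genome, the share of reads was 7.53% at day 0 and 11.6% at day 6. Windows placed at random outside both lists had 0.996 and 1.00 times the density of their flanks at day 0 and day 6.

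Windows of both lists were already enriched at day 0 and more so at day 6, with a read density of 4.36 and 5.60 times the flanks. Windows listed only at day 6 were not empty at day 0. They stood 1.97 times above their flanks at day 0 and 3.57 times at day 6. At day 0, 45.7% of them had a fold over the flank of at least 2, against 4.37% of the random windows. Only 58 of these windows had no day 0 read. Windows listed only at day 0 stood 2.99 times above their flanks at day 0 and 2.10 times at day 6. These folds need no scaling between the libraries, but each list was chosen on its own library, which raises its windows in that library.

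The read counts of day 6 against day 0 asked which sites gained or lost GPS2 during differentiation. By the size rule, 6662 of the 21227 merged windows were higher at day 6 (31.4%), 441 were lower (2.08%) and 14124 were neither. Counting error alone, drawn 100 times at the same depths, gave on average 822 higher and 1007 lower windows. These draws leave out how the windows were chosen: 13743 came from the day 6 list only and 2103 from the day 0 list only, which favours higher calls, so the draws are no test of the excess. A minimum of 20 reads gave 2321 higher and 100 lower windows, a ratio of 1.5 gave 10854 and 925, and flank subtraction 9176 and 996. Of the windows in both lists, 561 were higher and 22 lower. Of those in the day 6 list only, 6096 were higher and 2 lower, while in the day 0 list only 5 were higher and 417 lower. The median ratio was 1.33 for windows of both lists, 2.003 for the day 6 list only and 0.744 for the day 0 list only.

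Summed over all windows with a free flank, the ratio of day 6 to day 0 was 1.54 (1.54 to 1.55), against 0.963 (0.951 to 0.974) at the random windows. It was 1.35 (1.34 to 1.36) at windows of both lists, 1.97 (1.95 to 1.98) at windows of the day 6 list only and 0.749 (0.736 to 0.763) at windows of the day 0 list only. At the windows of the day 0 list, not joined with day 6 windows, it was 1.23 (1.22 to 1.24), but 0.921 after scaling by the median ratio of the windows in both lists. That scaling moved every log2 ratio by -0.42 and set the shared windows near 1 by construction. It left 3243 higher and 942 lower windows, so that 77.5% of the calls were higher in place of 93.8%. Among windows of the day 0 list alone, 566 were higher and 439 lower (56.3% higher).

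**Figure D2:**
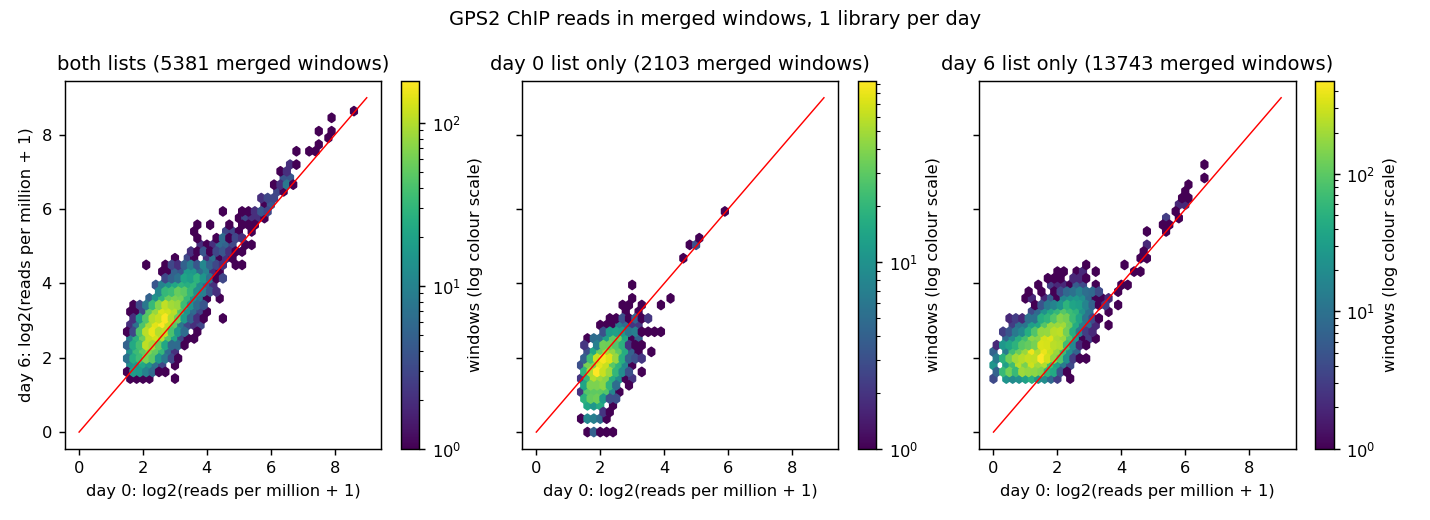
RPM in each merged window at day 0 (x axis) and day 6 (y axis), both as log2 of the value plus 1, for windows of both lists, of the day 0 list only and of the day 6 list only. Colour gives the number of windows per hexagon on a log scale, and the red line marks equal values. The median ratios are 1.33, 0.744 and 2.003.

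Across the 5381 windows of both lists, heights at day 0 and day 6 had a Pearson correlation of 0.851 and a Spearman correlation of 0.737, as log2 of RPM plus 1. Across all 21227 merged windows the values were 0.711 and 0.634. These are correlations across windows, which are not independent replicates.

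The 10 windows with the largest ratios all came from the day 6 list only. Their fold over the flank at day 0 was 0.286 to 0.870, for some of them taken against the genome mean. A window on chromosome 7 (51746208 to 51748207) rose from 1 read at day 0 to 21 at day 6, a ratio of 25.2 (4.06 to 1044). One on chromosome 12 (54628275 to 54630274) went from 2 to 27 reads, a ratio of 16.2 (4.08 to 141). One on chromosome 1 (87984947 to 87986946) went from 2 to 26 reads, a ratio of 15.6 (3.91 to 136). The window with the most day 6 reads of the 10, on chromosome 11 (105852124 to 105854123), went from 4 to 37, a ratio of 11.1 (3.99 to 42.9), and its density over the flank from 0.870 to 8.81. The other 6, with 2 day 0 reads each and ratios between 12.0 and 13.2, lay on chromosome 8 (3 windows), 11, 10 and 2. These 10 were the extremes of 7419 windows with at least 20 reads in one library, so their ratios overstate the change.

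Windows listed at day 6 without a day 0 counterpart were most numerous in a few 500 kb segments, which were chosen after their values were seen and not tested against chance. On chromosome 10, the stretch from 79000001 to 79500000 held 48 windows of the day 6 list against 11 of the day 0 list, and 40 of the 48 had no day 0 counterpart. The reads in its merged windows rose by a ratio of 1.93 (1.73 to 2.15). The 3 segments that follow it, up to 81000000, held 32, 34 and 39 windows without a day 0 counterpart, with ratios of 1.72, 1.88 and 1.85. Segments on chromosome 8 (87500001 to 88000000), chromosome 15 (78500001 to 79000000) and chromosome 17 (26500001 to 27000000) held 35, 34 and 32 such windows, with ratios of 1.53, 1.64 and 1.86, of which the first did not exceed the 1.54 over all windows. The chromosome 8 segment also held 31 day 0 windows. Others on chromosome 19 (5500001 to 6000000) and chromosome 8 (73000001 to 73500000 and 123000001 to 123500000) held 34, 34 and 33 windows without a day 0 counterpart. Their ratios were 1.57, 1.56 and 1.68. Background reads outside the windows also rose against the genome median in every one of these segments. In the chromosome 10 segment from 79000001 they were 1.90 times the genome median at day 0 and 2.88 times at day 6. In the chromosome 8 segment from 87500001 they were 2.07 and 2.44 times. The window ratios of these segments were not corrected for this rise.

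The smallest ratios were concentrated on chromosome 13, which held 46 of the 441 lower windows and 773 of the 21227 merged windows. Of the 10 smallest ratios, 7 lay there, between 21286213 and 23509476. The window from 23432894 to 23434893 fell from 39 reads to 7, a ratio of 0.216 (0.0814 to 0.488). Those from 23315573 to 23317572 and from 23473552 to 23475551 each fell from 20 reads to 3, a ratio of 0.180 (0.0343 to 0.608). The window from 23507477 to 23509476 went from 31 to 6 reads, a ratio of 0.233 (0.0793 to 0.566). The remaining 3 of the 10 lay on chromosome 19 (21669610 to 21671609, 20 to 4 reads), chromosome 11 (116883372 to 116885371, 28 to 6 reads) and chromosome 6 (47907710 to 47909709, 29 to 7 reads).

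The segment of chromosome 13 from 21000001 to 23500000, chosen after these values were seen, held 68 merged windows, 0.320% of all, but 28 of the 441 lower windows (6.35%), with 4 higher ones. Its windows together had a ratio of 0.777 (0.711 to 0.848), against 1.07 for windows of the same lists elsewhere, weighted as in the segment, and 1.54 over all windows. The lower windows themselves had 0.319 (0.263 to 0.383), which their selection lowers, and the background of the segment had 0.893 (0.845 to 0.943). In 99 of 100 random splits of the reads, 1 part had its largest number of lower windows in a 500 kb stretch of this segment, and the windows there had a median ratio of 0.636 (0.472 to 1.03 over the splits) in the other part. The windows themselves were listed on the reads of both parts, so the other part is not free of that selection. The segment was also found in these same reads, so choosing it again in 99 splits is no replication. No 500 kb segment outside the chromosome 13 segment held more than 4 lower windows. Shuffling the calls among windows of the same list 1000 times gave at most 7 lower windows in any 500 kb segment, while 10 were observed from 23000001 to 23500000.

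**Figure D3:**
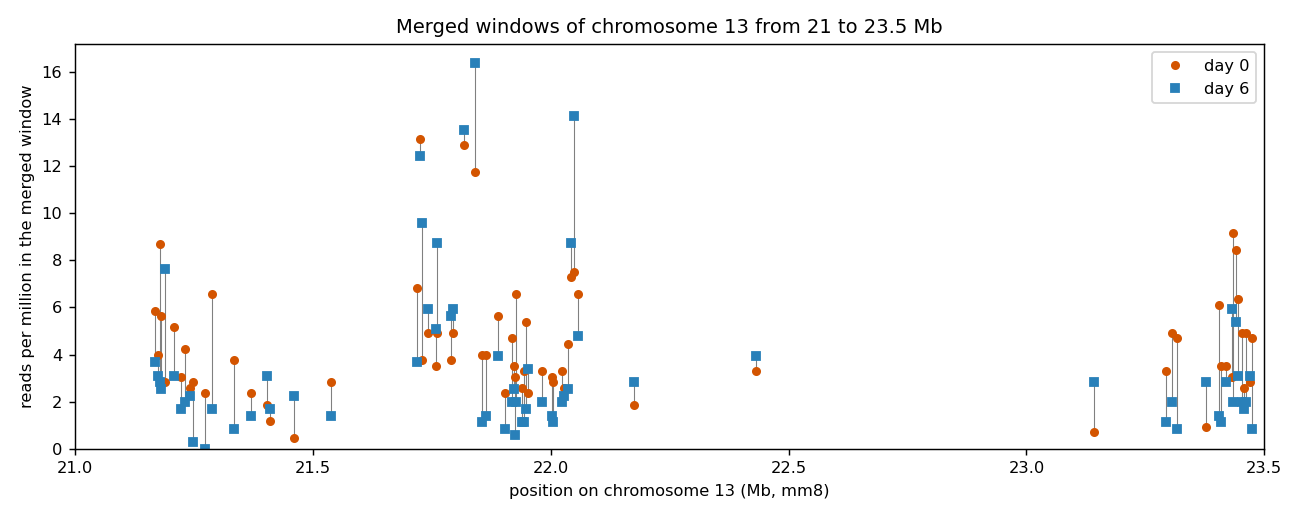
RPM in each merged window (y axis) against its position on chromosome 13 in Mb of mm8 (x axis), for the segment from 21000001 to 23500000. Orange circles are day 0 and blue squares day 6, joined by a line for each of the 68 windows, of which 28 are called lower and 4 higher.

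The windows with the most reads were nearly the same at both days. No input library was analysed, so reads piled up there for other reasons cannot be told from GPS2 binding. Of the 10 windows with the most day 6 reads, 9 were also among the 10 with the most day 0 reads. On chromosome 5 the window from 3000173 to 3002223 held 1551 reads at day 0 and 1448 at day 6, a ratio of 1.12 (1.04 to 1.21). On chromosome 14 the window from 18208524 to 18210562 held 924 and 862 reads, a ratio of 1.12 (1.02 to 1.23). Its fold over the flank was 280 and 314, taken against the genome mean because its flanks were sparser. On chromosome 2 the window from 98466581 to 98468814 held 958 and 950 reads, a ratio of 1.19 (1.09 to 1.30), at only 6.53 and 6.88 times its flanks. The window on chromosome 17 from 13342497 to 13346326 rose from 986 to 1220 reads, a ratio of 1.49 (1.37 to 1.62), and one on chromosome 2 from 22438397 to 22442356 from 760 to 948, a ratio of 1.499 (1.36 to 1.65). The largest ratio among these was 1.72 (1.53 to 1.95), on chromosome 13 from 74993761 to 74997333, with 457 and 655 reads. With at most 1 read per position and strand, counts in such dense windows are capped, which pulls the counts of both libraries towards each other. Because the day 6 library is smaller, equal counts give a ratio above 1, as the 958 and 950 reads with 1.19 show.

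Background reads asked whether the libraries were comparable outside the bound regions. In 237186 bins of 10 kb outside the windows the libraries held 14.5 and 11.4 reads per bin at day 0 and day 6. Relative to this total, the ratio of day 6 to day 0 was highest on chromosome 11, at 1.06 (1.06 to 1.07), and lowest on chromosome X, at 0.938 (0.931 to 0.945). In 100 kb bins this ranking was lost: chromosome 18 was highest, at 1.06 (1.05 to 1.07), and chromosome 16 lowest, at 0.951 (0.941 to 0.961). In 10 kb bins chromosome 8 (1.23 and 1.17 times the chromosome median at day 0 and day 6) and chromosome 15 (1.20 and 1.18) had the densest background, while in 100 kb bins chromosome 9 (1.20 and 1.23) was densest at day 6 and chromosome 15 (1.21 and 1.19) at day 0. Chromosome 12 (0.803 and 0.789), chromosome X (0.685 and 0.627) and chromosome Y (0.350 and 0.333) had the sparsest in 10 kb bins.

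A stretch of 600 kb on chromosome 10, from 116600001 to 117200000, stood 44.7 times above the genome median at day 0 and 50.9 times at day 6. It took 1.00% of all reads at day 0 and 1.11% at day 6. It held 54 merged windows, among them 3 of the 10 windows with the most day 0 reads and 3 of those with the most day 6 reads. Its window from 117112266 to 117114487, with 763 and 810 reads, stood only 2.73 and 3.25 times above its flanks.

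**Figure D4:**
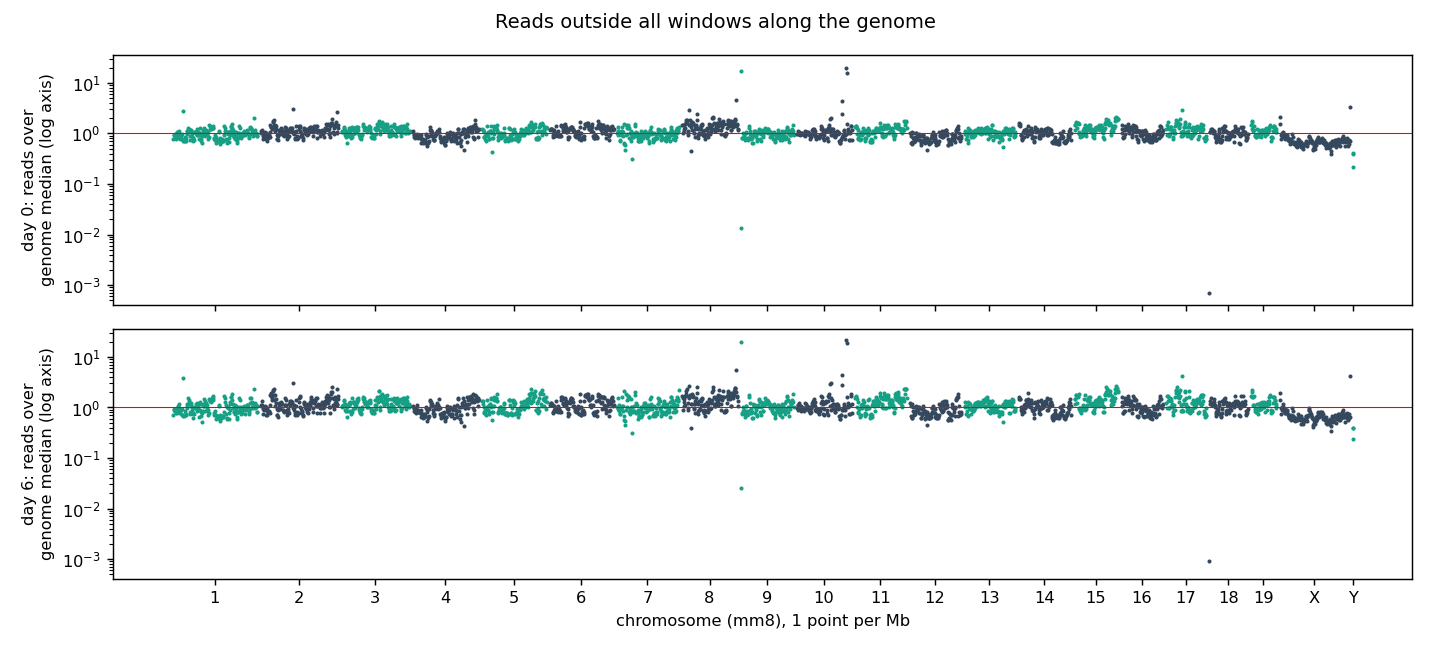
Reads outside all windows in each Mb of the genome, divided by the genome median (y axis, log scale), in chromosome order (x axis, mm8), at day 0 (top) and day 6 (bottom). Colours alternate between chromosomes. A point above 10 also lies at the start of chromosome 9. The points above 10 on chromosome 10 hold the segment that stood 44.7 and 50.9 times above the median, and chromosome X lies below the line at 0.685 and 0.627 of the chromosome median.

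Chromosomes with a denser background had more windows. Across the 20 chromosomes, windows per Mb of the day 0 list rose with day 0 background reads per Mb, with a Pearson correlation of 0.882 and a Spearman correlation of 0.862. Both had a permutation p of 1e-05, the smallest the permutations can give, and an adjusted p of 2e-05. For the day 6 list the values were 0.865 and 0.848, with the same p and adjusted p. Without the 2 chromosomes farthest from the median the Pearson correlation was 0.812 (day 0, without 8 and X) and 0.816 (day 6, without 12 and X).

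The relation to gene density was weaker. With protein-coding genes per Mb, counted in GRCm38.p6, windows per Mb of the day 0 list had a Pearson correlation of 0.417 (permutation p = 0.0685, adjusted p = 0.0685) and a Spearman correlation of 0.544 (permutation p = 0.0146, adjusted p = 0.0146). For the day 6 list the Pearson correlation was 0.555 (permutation p = 0.0111, adjusted p = 0.0148) and the Spearman correlation 0.695 (permutation p = 0.0009, adjusted p = 0.0012). Without chromosomes 7 and 11 the Pearson correlations were 0.546 and 0.628. In all, 4 relations were computed. The difference between the days was not tested.

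**Figure D5:**
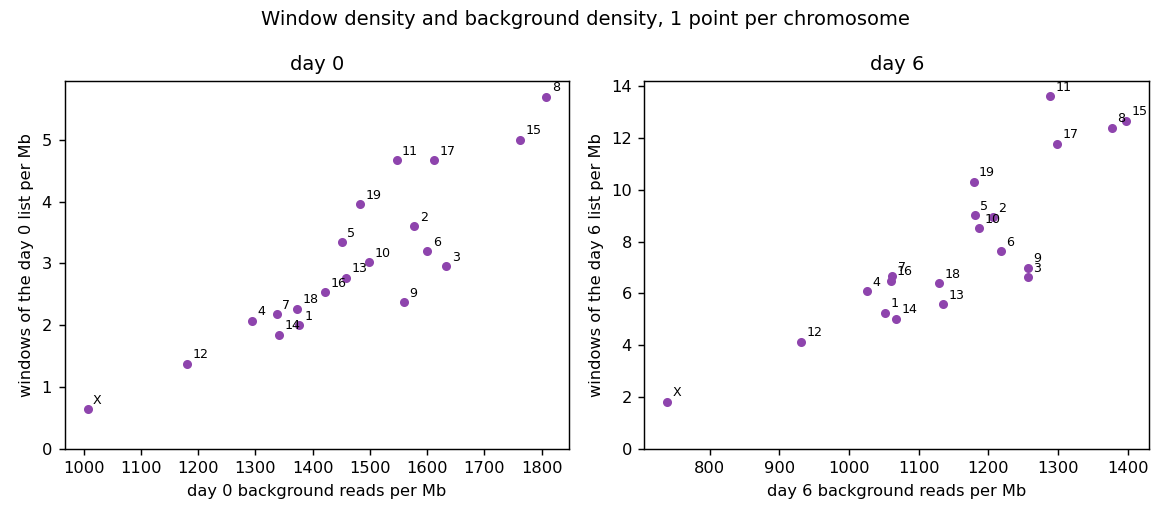
Windows per Mb (y axis) against background reads per Mb (x axis), 1 labelled point per chromosome, for day 0 (left) and day 6 (right). The Pearson correlations are 0.882 and 0.865, with chromosome X lowest on both axes in both panels.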

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

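The mitochondrial genome, which carries no window of either list and enters none of the comparisons, held more reads than the 3 that a count of 0 allows. It took 10602 reads at day 0, 0.249% of the library (0.244 to 0.254), and 12566 reads at day 6, 0.355% (0.348 to 0.361). The ratio of day 6 to day 0 was 1.42 (1.39 to 1.46), and 1.49 after correcting for positions that were already filled, since 32.5% and 38.5% of all mitochondrial positions and strands held a read. With 1 library per day, the spread of this share between cultures is unknown.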

How the results depend on the processing

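Alternatives marked as added were chosen after seeing the data, and where a value changed the cause was not tested unless the construction gives it. Scaling by the median ratio of the windows in both lists left 3243 higher and 942 lower windows, and, since it multiplies every ratio by 0.749, put the ratio at windows of both lists at 1.01, that of all merged windows at 1.15 and that of the day 0 list at 0.934, below 1 by arithmetic. Scaling by reads outside the windows gave ratios of 1.30 (day 0 list), 1.41 (both lists) and 1.61 (all), and subtracting the flanks gave 1.31, 1.44 and 1.80, with 9176 higher and 996 lower windows. Within 500 bp of the centre the ratio was 1.38 for both lists and 1.66 for all. A minimum of 20 reads left 2321 higher and 100 lower windows, and a ratio of 1.5 gave 10854 and 925. Keeping only windows of the day 0 list (added) left 566 higher windows, and not joining the day 0 windows with day 6 windows (added) gave a ratio of 1.23. Without windows of at least 100 reads (added) the 3 ratios were 1.24, 1.36 and 1.58. Without the dense 600 kb stretch of chromosome 10 (added) the ratio of all windows was 1.55. Sharing at least 50%, or centres within 1 kb, lowered the overlap to 69.2% of the day 0 list and 26.7% of the day 6 list under either rule. Among the 5000 windows of each list with the highest fold over the flank (added), 50.3% and 50.4% overlapped. A fold over the flank of at least 8 (added) left 627 windows at day 0 and 2506 at day 6. In 100 kb bins the background ratio was 1.04 for chromosome 11 and 0.964 for chromosome X, neither of them still the highest or lowest. Of the main values under these alternatives, 17 stayed within 1.5 times the count or within the 95% interval, 33 moved beyond that and 1 (the 0.934) changed sides of 1. All 60 values of the 20 windows with the largest and smallest ratios stayed within their intervals. That is no sign of stability, since these intervals were wide and the scalings only multiplied each ratio by a constant. Within 500 bp of the centre, the ratio on chromosome 12 (54628275) went from 16.2 to 32.4. One on chromosome 8 (13467430) went from 12.0 to 6.41. No paired analysis was possible because there was 1 library per day. Not run were a peak score or fold from the lists (they hold none), 1 read per position (already so) and distances to gene starts or gene lists (no mm8 annotation was used here).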

Other observations

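All tests in this part were chosen after the results were seen. The longer day 6 list may follow from a stronger enrichment of the day 6 library at sites already bound at day 0. The day 6 library did not hold more deposited reads, with 0.832 times those of the day 0 library. With at most 1 read per position and strand, these counts do not give the sequencing depth, so they cannot decide on deeper sequencing. At windows of the day 0 list, not joined with day 6 windows, the ratio of day 6 to day 0 after subtraction of the flanks was 1.28, and the density over the flanks was 4.28 times at day 0 and 5.01 at day 6, which needs no scaling between libraries. A laxer peak threshold at day 6 is argued against as the whole cause. With a fold over the flank of at least 8, the day 6 list kept 3.997 times as many windows as the day 0 list. This factor (3.66 to 4.37) lay above the 2.59 times of the full lists. A rise of GPS2 on chromatin during differentiation and a more efficient immunoprecipitation at day 6 would both give a longer day 6 list. With 1 library per day neither was tested against the other.

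The fall of windows on chromosome 13 from 21000001 to 23500000 might follow a feature of this segment. Fewer DNA copies at day 6 would lower background and windows alike. The background of the segment had 0.938 times (0.888 to 0.991) the genome's background ratio. All its windows had 0.724 times (0.663 to 0.790) the ratio that windows of the same lists had elsewhere. Choosing the segment for its lower windows lowers the 0.724 but not the 0.938. The gap is therefore overstated, and fewer copies are not excluded as the whole cause. Chance highs at day 0 are argued against for the stretches from 23000001 and 21500001, which held 10 and 9 lower windows. All merged windows of the first together had a ratio of 0.548 (0.447 to 0.669). Those of the second had 0.904 (0.791 to 1.03), an interval that includes 1. Shuffled calls reached at most 7 in a 500 kb segment. The stretch from 21000001 held 7, so the shuffles do not speak for it. In 288 of 1000 shuffles some segment reached 5 or more. In GRCm38.p6, chromosome 13 carries 54 of 67 histone genes and 105 of 408 tRNA genes. Histone promoters stay open: 3.57% of the lower windows (1 of 28, 0.0904 to 18.3) lay within 1 kb of a point inferred from the list order, but these points were not matched to genes. For tRNA genes the test also leaves the question open: across 20 chromosomes, lower windows with at least 20 day 0 reads had a Pearson correlation with tRNA genes of 0.777 (permutation p = 0.00021, adjusted p = 0.00042) and a Spearman correlation of 0.399 (permutation p = 0.083, adjusted p = 0.166), with a Pearson correlation of 0.449 without chromosomes 6 and 13. Without chromosome 13 alone the Pearson correlation was 0.601 (permutation p = 0.00581, adjusted p = 0.00581) and the Spearman correlation 0.298 (permutation p = 0.216, adjusted p = 0.216).

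The order of the deposited lists may encode the signed distance of each window to the nearest gene start. Windows close together on a chromosome had places in the lists that differed by an amount matching their separation: a curve fitted on part of the neighbouring pairs matched 67.4% of 4243 held-out pairs under 10 kb apart, within 10% plus 20 bp, against 1.34% after shuffling the order. Over all 11685 held-out pairs the shares were 47.1% and 5.51%, and for the 7442 pairs at least 10 kb apart 35.6% and 7.89%, so larger distances are less certain. The points could be gene starts, since the share of windows within 1 kb of a point rose with protein-coding genes per Mb across 20 chromosomes, with a Spearman correlation of 0.740 (permutation p = 0.00043, adjusted p = 0.00086) and a Pearson correlation of 0.593 (permutation p = 0.0059, adjusted p = 0.0118; 0.543 without the 2 farthest chromosomes) for the day 0 list. For the day 6 list the Spearman correlation was 0.511 (permutation p = 0.023, adjusted p = 0.023) and the Pearson correlation 0.514 (permutation p = 0.02055, adjusted p = 0.02055), which was 0.404 without the 2 farthest chromosomes. The inferred points themselves were not matched to genes. List order gives distances only up to a constant. Zero was therefore placed at the centre of the densest stretch of both lists, and every share within 1 kb rests on that choice.

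If this reading holds, and if gene starts lie where zero was placed, 50.3% of the day 0 list (3849 windows, 49.2 to 51.4) would lie within 1 kb of a gene start. For the day 6 list it would be 38.2% (7558 windows, 37.5 to 38.9). Beyond 10 kb the shares would be 35.4% and 44.0%. Of the day 0 windows within 1 kb, 85.01% were found again at day 6, against 57.3% of those beyond 10 kb. Of the merged windows within 1 kb, 27.0% were called higher (26.1 to 28.0) and 1.13% lower, against 36.1% and 2.47% from 1 to 10 kb, and 33.3% (32.4 to 34.3) and 2.73% beyond 10 kb. The summed ratios in these classes were 1.52, 1.59 and 1.55. Within 1 kb and beyond 10 kb they were 1.31 (1.30 to 1.32) and 1.16 (1.15 to 1.18) for the day 0 list, but 1.59 (1.58 to 1.60) and 1.69 (1.67 to 1.699) for the day 6 list, so the direction depended on the list. Near windows of the day 6 list held more reads (median 15 and 20 at day 0 and day 6, against 8 and 13). On simulated lists ordered by such a distance the estimate was 41.0% where the true share was 41.2%, but lists in random order also gave 20.3% and 25.4%, so the share alone is no sign of such an order. The simulated windows were made to crowd around the points, so they cannot check where zero was placed. In the segment of chromosome 13, the 21 windows within 1 kb had a ratio of 1.32 (1.16 to 1.503), and the other 47 a ratio of 0.491 (0.432 to 0.556). The segment was chosen for its lower windows, of which only 3.57% lay within 1 kb. That choice lowers mainly the 0.491, and the interval does not cover it.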
